A study of Homo sapiens with 4 samples.

How the data were processed

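Ribosome-protected RNA fragments (footprints) were sequenced from A375 cells, an established human melanoma line, grown for 48 h in control medium or in medium without arginine, with 2 libraries per group. Groups and replicate numbers came from the sample titles. Nothing in the labels says that the replicates are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

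The deposited values are counts, made by the authors with featureCounts 2.0.1 over the exons of the GENCODE 47 basic annotation without strand, per the file headers. The submitters' processing notes name cutadapt, Bowtie2 2.5.2, TopHat2 and the builds GRCh37 and hg19. The labels' protocols describe footprint libraries made without removal of ribosomal RNA and read as single reads. The header also shows the option for paired reads, and its effect on the counts was not tested. The deposited table holds 78724 gene identifiers with coordinates, and 9443 of them have a count above 0 in any library. Values were used as whole-number counts with no upstream normalization.

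The identifiers came without gene symbols. Rows were named by place, against the RefSeq gene table of GRCh38.p14. A row took a symbol when it and a RefSeq gene were each other's best match, with an overlap over union of at least 0.5 where a start or an end was shared exactly, and of at least 0.75 where neither was. This named 38583 rows, of which 18311 were protein-coding, and 88.3% of the protein-coding matches shared a start or an end exactly. The RefSeq table used carries no strand, and coordinates printed are those of the deposited table. The place of a row is therefore on GRCh38, while the processing notes name GRCh37 for the reads. No coordinates were converted between builds.

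Because many broadly expressed genes were listed at 0, the rows that could be read as genes were limited after the data were seen. Across 19 of the lists described next, 656 nuclear genes, most but not all of them used by most dividing cells and called anchors here, were ordered along the chromosomes. A stretch was a run of at least 5 neighbouring anchors that each held 20 or more reads over the 4 libraries. Gene names are used for rows inside the 5 nuclear stretches and on the mitochondrial chromosome, and elsewhere a row is described only by its identifier's place. Whether mitochondrial coordinates are the same in both builds was not checked. A shift between builds shorter than a gene would still leave part of a gene's reads in its row, so a row need not hold all reads of its gene.

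Rows were tested with edgeR 4.0.16 (R 4.3.3), using TMM factors, filterByExpr by group, and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are given on the log2 scale with standard errors (SE). These were worked back from the test, as the absolute log2 fold change over the square root of its F statistic. They may be too small where counts are near 0. Levels are given as CPM, which are counts scaled by the total of the tested rows in a library and its TMM factor. A fold change is 2 to the power of the fitted log2 fold change, unless another ratio is named, so it can differ from the ratio of the mean CPM printed beside it. The comparisons, the rule for named genes, the alternatives and 34 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists. Camera with the correlation estimated from the libraries was run beside it. With 2 libraries per group that form has few degrees of freedom and can hardly pass. A list that did not pass it is therefore not shown to be unchanged. Shares of counts per gene class carry 95% Wilson intervals, which cover counting error only, since fragments amplified without molecular identifiers are not independent molecules. Tables were handled with Python 3.11.15 and pandas 2.3.3.

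Genes named in the text follow 1 rule. It takes the 12 highest and the 12 lowest log2 fold changes among protein-coding genes past the threshold whose libraries of one group both lie above both of the other, with a mean count of at least 50. It adds up to 4 members of each described list and 12 genes of arginine metabolism, the amino acid stress response and melanoma. The limit to the stretches was added later, and 10 genes were then left among the higher ones. Genes named outside this rule are said to be so.

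The total count per library was 105004 and 217989 in control medium, and 234766 and 192006 in arginine-free medium. A count of 0 allows up to 3 counts, which is 28.6 CPM of all rows in the shallowest library and 12.8 CPM in the deepest. The test was tried on simulated counts for the 2526 tested rows with 200 rows changed. It recovered 86% of the 4-fold changes and 22% of the 2-fold changes, with 5 calls among the unchanged rows. Every simulated row was given the same dispersion (0.034), while some real rows vary more between libraries. For such rows the recovery may be lower and false calls more frequent.

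Alternatives covered the scaling (RLE, upper-quartile, library totals), the tool (DESeq2 1.42.0, limma-voom), the filter, the replicate number as a block, each library left out in turn, protein-coding nuclear rows alone, thinning to the lowest total, and a test against a fold change of 1.5. DESeq2 was given all 9443 rows with a count above 0, so that setting changed the filter as well as the tool. The planned comparison of fold change with arginine content was not run, as coding sequences were not used here. Translational efficiency was not analysed here, so a footprint change can come from the amount of an mRNA or from its translation.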

Results

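Ribosome profiling was used to ask how translation in A375 melanoma cells differs after 48 h without arginine, an amino acid that cells lacking the enzyme ASS1 cannot make from citrulline. Footprints were counted in 2 libraries of cells in control medium and 2 of cells in arginine-free medium. Total counts were 105004 and 217989 for control replicates 1 and 2, and 234766 and 192006 for arginine-free replicates 1 and 2.

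Reads were found at only part of the genes that dividing cells use. Of 72 rows matched to cytosolic ribosomal proteins, 52 held no read, while RPS6 on chromosome 9 held 3361 reads, RPS15 on chromosome 19 held 4943 and RPL37 on chromosome 5 held 1517. Over 656 nuclear genes from lists of mostly broadly expressed genes, 449 (68.4%) were listed at 0, and 67.9% of 564 without the lists of stress-induced genes. The processing notes name GRCh37, and the coordinates in the table match GRCh38, so a row is read here as its gene only inside 5 nuclear stretches where each of at least 5 neighbouring genes of these lists held 20 or more reads, and on the mitochondrial chromosome. These stretches run from SDHA to HMGCS1 (chromosome 5, 218303 to 43313512), H1-1 to H4C3 (chromosome 6, 26017032 to 26104337), H2BC7 to H2BC10 (chromosome 6, 26199516 to 26273412), VLDLR to VCP (chromosome 9, 2621567 to 35072668) and ATP5F1D to CHAF1A (chromosome 19, 1241746 to 4443397). They hold 1798 rows and 13.2% of the nuclear reads. Those on chromosomes 5 and 19 rest on 5 such genes each, the fewest allowed. Either would be lost if any of its 5 had held fewer than 20 reads. No other minimum of reads or of run length was tried.

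**Figure D1:**
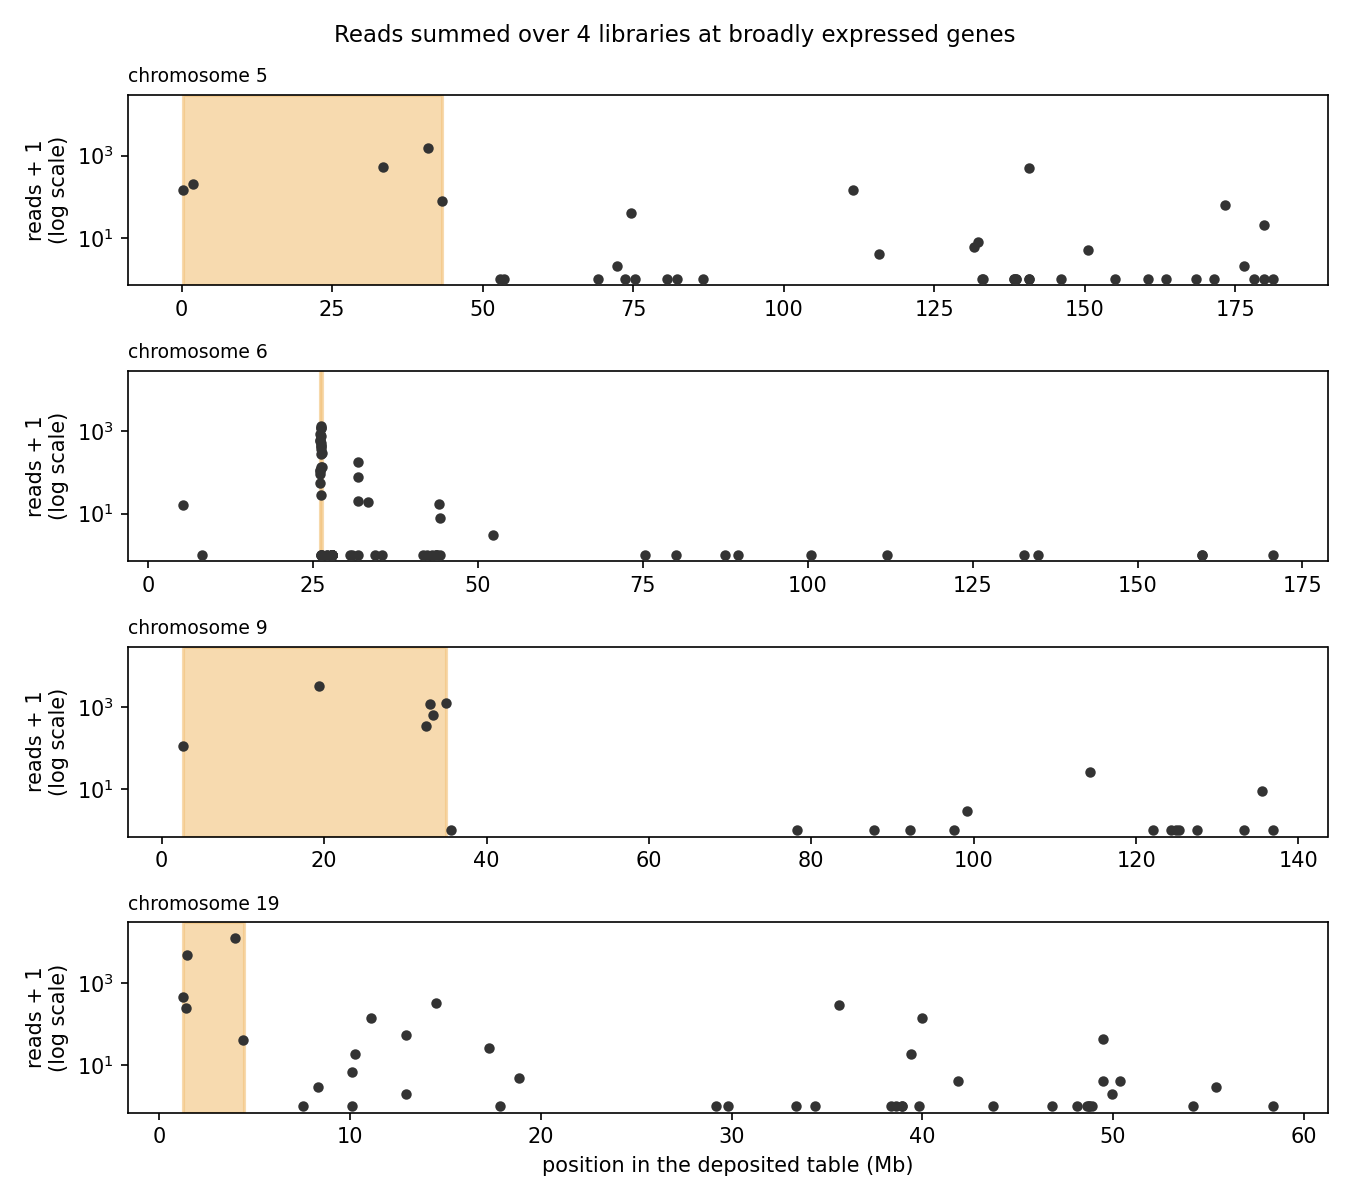
Reads summed over the 4 libraries plus 1 (y axis, log scale) at the genes of these lists along chromosomes 5, 6, 9 and 19 (x axis, position in Mb in the deposited table). Each point is 1 gene and shaded spans are the 5 stretches. Inside them each of the 33 genes held at least 20 reads by definition. Of the 623 genes outside the stretches, over all chromosomes, 449 held none.

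The clearest difference between the media was in the replication-dependent histones, the DNA-packaging proteins made mainly while DNA is copied. In the stretches on chromosome 6, 15 of 16 tested histone genes fell in arginine-free medium and 1 did not pass the test, and the median log2 fold change was -3.28. Some of the histone genes that define these stretches reached 20 reads only through the control libraries. Among them were H3C2, with 4 and 10 reads in arginine-free medium, and H3C8, with 5 and 3. Footprints on H3C2 (chromosome 6, 26031589 to 26032099) fell from 1927 ± 154 to 40.1 ± 32.2 CPM (SD, n = 2 each), 51.7-fold lower by the fitted log2 fold change of -5.69 (SE 0.37, edgeR adjusted p = 1.14e-07). H3C2 stood at -4.88 without arginine-free replicate 1 and at -6.69 without arginine-free replicate 2, and passed in both. H3C8 changed by -5.44 (SE 0.33) and H3C3 by -4.43 (SE 0.26) on the log2 scale, and H2BC8 went from 1540 ± 154 to 178 ± 6.31 CPM (SD, n = 2 each). The linker histone H1-3 went from 3349 ± 71.9 to 588 ± 109 CPM (SD, n = 2 each), a log2 fold change of -2.51 (SE 0.24). The H4 gene H4C3 changed by -1.29 (SE 0.24). H4C6 and H4C5 were chosen after their values were seen. H4C6 changed by -1.10 (SE 0.21), and H4C5 had 1737 ± 48.9 and 1848 ± 567 CPM (SD, n = 2 each, edgeR adjusted p = 0.815).

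Over the whole table, 18 of 19 tested histone rows were lower, and the count adjusted over the list alone was also 18. The list passed camera at the preset correlation, with an adjusted p of 1.73e-28 and a median log2 fold change of -3.11. It did not pass with the correlation between its members estimated from these libraries (camera unadjusted p = 0.0625, adjusted p = 0.625 with an estimated correlation). With 2 libraries per group that form of the test has little power, so it cannot decide whether the list shifted. Histone genes are near-identical copies of each other, so the value of a single copy is uncertain, and 19 of 39 histone rows in the table were listed at 0. These rows are also short, so if reads were placed on another build, a row may hold only part of its gene's reads. The size of a single gene's change, and differences between histone genes, are uncertain for this reason too.

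**Figure D2:**
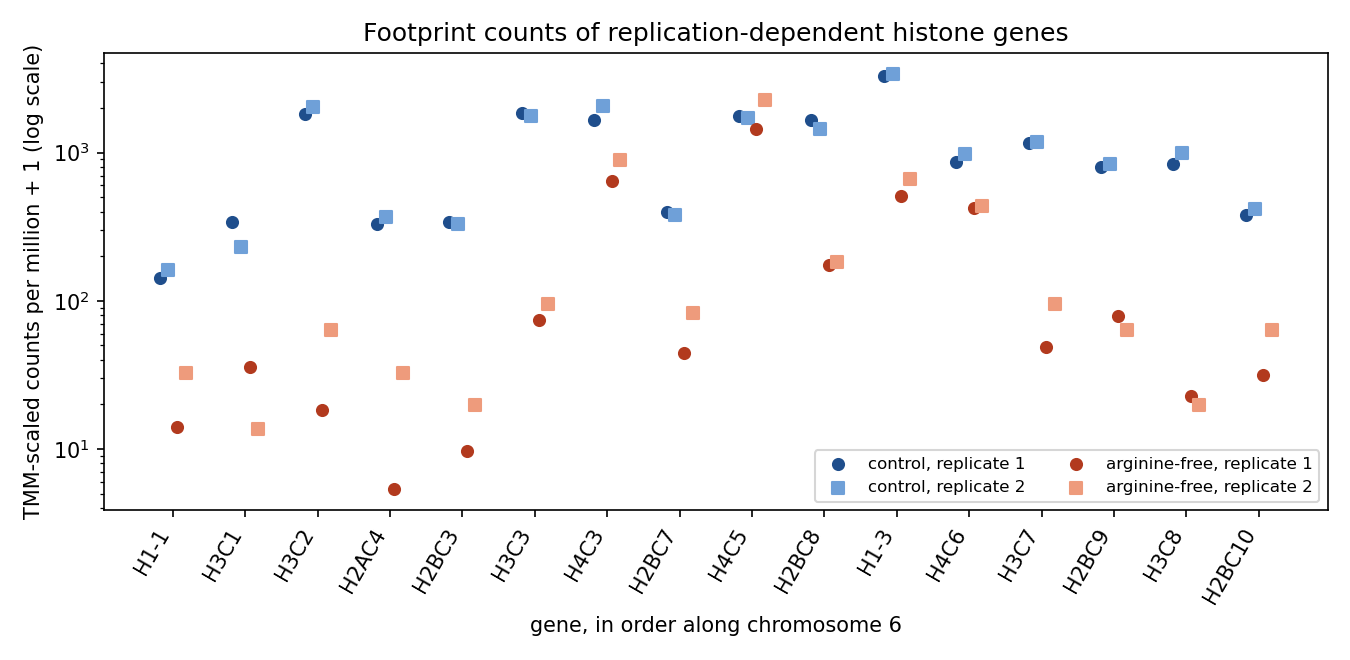
CPM plus 1 (y axis, log scale) of the 16 tested histone genes in the stretches, in order along chromosome 6 (x axis). Circles are replicate 1 and squares replicate 2, blue for control and red for arginine-free medium. Both arginine-free libraries lie below both control libraries in each gene except H4C5.

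Footprints rose on some genes of the translation machinery, and none of their lists that could be tested passed camera. RPL37, a protein of the large ribosomal subunit (chromosome 5, 40825262 to 40835222), rose 3.67-fold, from 862 ± 7.48 to 3160 ± 498 CPM (SD, n = 2 each, log2 fold change 1.88, SE 0.23, edgeR adjusted p = 3.9e-05). RPS6, a small-subunit protein phosphorylated downstream of mTORC1 (chromosome 9, 19375715 to 19380236), rose 2.11-fold, from 3053 ± 401 to 6427 ± 797 CPM (SD, n = 2 each). The elongation factor EEF2 (chromosome 19, 3976056 to 3985463) rose 2.05-fold, from 11653 ± 741 to 23893 ± 2008 CPM (SD, n = 2 each). RPS15, also chosen after its values were seen, had a log2 fold change of 0.42 (SE 0.25, edgeR adjusted p = 0.225), and from 0.17 to 0.67 over the alternatives. The threonyl-tRNA synthetase TARS1 and the ribosome assembly factor NOL6, chosen in the same way, stood at 0.18 (SE 0.21) and 0.51 (SE 0.22) and did not pass. Adjusted over the list alone in the stretches, where each is the 1 tested member of its list, NOL6 was higher and TARS1 did not pass. MRPL36, of the mitochondrial ribosome, rose by a log2 fold change of 1.22 (SE 0.28). ZNF622, a factor of large-subunit maturation that is in none of the lists, rose 4.16-fold, from 292 ± 13.8 to 1213 ± 105 CPM (SD, n = 2 each).

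Of the 3 ribosomal protein genes in the stretches, 2 rose and 1 did not pass, and adjusted over the list alone the count was also 2. The ribosomal protein list over the whole table had 7 tested rows, of which 2 were higher and 2 lower, and it did not pass camera (adjusted p = 0.752). The translation factors had 1 higher and 1 lower of 7 tested (adjusted p = 0.994), and ribosome biogenesis 2 and 2 of 8 (adjusted p = 0.865). The calls for RPS6, EEF2 and MRPL36 ended without control replicate 2, at edgeR adjusted p of 0.0549, 0.0542 and 0.0667, and EEF2 also without control replicate 1 (adjusted p = 0.0676). MRPL36 also did not pass with DESeq2 (adjusted p = 0.0627). RPL37 shares its place with the small nucleolar RNA SNORD72, whose row also rose, by a log2 fold change of 1.14 (SE 0.30). If reads were placed on another build, the reads of such a short row need not come from SNORD72.

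Genes of arginine and polyamine handling moved in both directions. OAZ1, the antizyme that brakes polyamine synthesis and is itself made by a frameshift that polyamines promote (chromosome 19, 2269520 to 2273490), rose 2.7-fold, from 390 ± 21.8 to 1049 ± 80.4 CPM (SD, n = 2 each, edgeR adjusted p = 0.000247). GAMT, the last enzyme of creatine synthesis, which starts from arginine and glycine (chromosome 19, 1397026 to 1401570), was 5.05-fold lower by the fitted change, at 170 ± 27.6 and 36.9 ± 27.7 CPM (SD, n = 2 each, edgeR adjusted p = 0.00206). These were the 2 tested genes of the arginine, proline and polyamine list inside the stretches, and both also passed when adjusted over the list alone. The GAMT log2 fold change of -2.34 (SE 0.48) became -1.57 without arginine-free replicate 1 and -3.23 without arginine-free replicate 2, and its call ended with DESeq2 (adjusted p = 0.0732).

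The lipoprotein receptor VLDLR, the member of the amino acid stress response list that lies in a stretch (chromosome 9, 2621567 to 2660056), rose 6.45-fold, from 39.4 ± 2.36 to 256 ± 78.4 CPM (SD, n = 2 each, log2 fold change 2.69, SE 0.41, edgeR adjusted p = 0.000241). VLDLR is also the first gene that defines its stretch, and it reached 20 reads only through the arginine-free libraries. Without the lists of stress-induced genes the stretch begins at RPS6, and VLDLR, PLIN2 and TYRP1 lie outside it. Between VLDLR and RPS6, 22.2% of 45 protein-coding rows were at 0, against 72.7% outside the stretches. PLIN2, which coats lipid droplets (chromosome 9, 19115761 to 19127492), rose 2.8-fold, from 765 ± 56.2 to 2148 ± 160 CPM (SD, n = 2 each). HMGCS1, an early enzyme of cholesterol synthesis (chromosome 5, 43287470 to 43313512), was 3.83-fold lower, with a log2 fold change of -1.94 (SE 0.39, edgeR adjusted p = 0.00167), a call that ended with DESeq2 (adjusted p = 0.0876).

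Footprints on TYRP1, a melanosome enzyme and the 1 tested member of the melanocytic list (chromosome 9, 12693385 to 12710285), fell. It lies in the part of the chromosome 9 stretch that depends on VLDLR. The row had 16 and 25 reads in control medium and 1 and 0 in arginine-free medium. That is 54.2-fold lower by total counts, with an exact 95% counting interval from 9.19 to 2191 (edgeR adjusted p = 0.000104). The log2 fold change of -5.39 (SE 0.75) became -4.72 without arginine-free replicate 2. Without arginine-free replicate 1 the row has 0 reads in that medium, so no fold is given, and the call stayed. MFSD12, which carries cysteine into melanosomes (chromosome 19, 3544199 to 3557586), was 3.48-fold lower, from 3054 ± 613 to 878 ± 170 CPM (SD, n = 2 each, log2 fold change -1.80, SE 0.25).

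Among other genes of the stretches, HMG20B, a chromatin protein (chromosome 19, 3572944 to 3579083), was 5.92-fold lower, from 1238 ± 89.2 to 213 ± 80.7 CPM (SD, n = 2 each). ATP5F1D, a subunit of ATP synthase, was 3.99-fold lower (log2 fold change -2.00, SE 0.25), and SDHA, of respiratory complex II, changed by -1.12 (SE 0.30). NDUFB6 and NDUFS7, of respiratory complex I and chosen after their values were seen, had log2 fold changes of -0.20 (SE 0.27) and -0.06 (SE 0.26) and did not pass. Of the 4 nuclear oxidative phosphorylation genes in the stretches, 2 thus fell, and adjusted over the list alone the count was also 2. The motor protein gene MYO10 changed by -1.47 (SE 0.22). SF3A2, THOP1 and MIDN were higher, with log2 fold changes of 0.92 (SE 0.23), 1.08 (SE 0.27) and 0.77 (SE 0.22). Without control replicate 2 the calls ended for SDHA, SF3A2, THOP1 and MIDN, at edgeR adjusted p of 0.0645, 0.131, 0.0621 and 0.259. With DESeq2 SDHA, THOP1 and MIDN did not pass either (adjusted p = 0.253, 0.0851 and 0.0743).

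**Figure D3:**
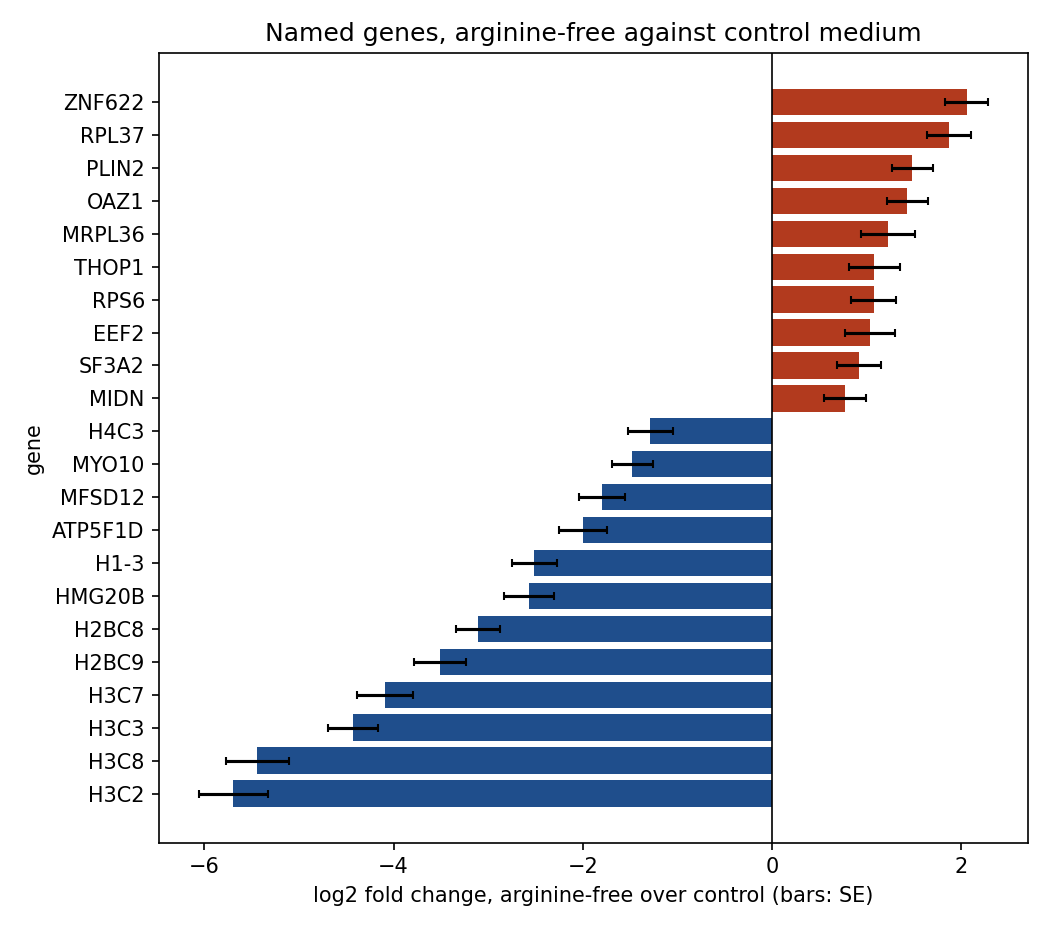
Log2 fold change of arginine-free over control medium (x axis) for the 22 protein-coding genes in the stretches with the largest changes that met the rule for named genes (y axis). Error bars are the standard error worked back from the test. Values run from -5.69 for H3C2 to 2.06 for ZNF622.

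Mitochondrially encoded proteins had a median log2 fold change of -0.62, and 3 of 13 were past the threshold, all lower: COX1 at -1.07 (SE 0.29), ND2 at -0.88 (SE 0.29) and ATP6 at -0.94 (SE 0.33). Adjusted over the list alone, 7 of 13 were lower. The list did not pass camera (adjusted p = 0.134, and adjusted p = 0.918 with an estimated correlation). The change was larger in arginine-free replicate 2. Without that library the median was -0.30 and ND2 and ATP6 no longer passed (edgeR adjusted p = 0.199 and 0.237). Without arginine-free replicate 1 the median was -1.0 and the list passed (adjusted p = 0.000115), with ND2 at -1.53 and ATP6 at -1.82. It also passed without control replicate 2 (adjusted p = 0.0297), where ND2 did not (edgeR adjusted p = 0.186). Both of these list calls are at the preset correlation, and with all 4 libraries the list had adjusted p = 0.918 with an estimated correlation of 0.829. Without control replicate 1, COX1 and ATP6 did not pass (edgeR adjusted p = 0.0686 and 0.107). With DESeq2, ND2 and ATP6 did not pass (adjusted p = 0.24 and 0.269). The ATP6 call also ended with RLE and with upper-quartile factors (edgeR adjusted p = 0.0651 and 0.0597).

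The 5 nuclear stretches had 196 tested rows, of which 28 rose and 46 fell. Among the 175 tested protein-coding genes there, 24 rose and 39 fell. The 2 histone stretches on chromosome 6 gave 20 of the 46 lower rows and no higher one, and the other 3 stretches had 28 higher and 26 lower. DESeq2 called 12 rows there higher and 28 lower, and without control replicate 2 edgeR called 18 higher. Over all chromosomes, 2526 rows were tested, and 405 were higher and 428 lower in arginine-free medium (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). DESeq2, given 9443 rows and not the 2526, called 162 higher and 147 lower, and without control replicate 2 edgeR called 243 lower. Outside the stretches and the mitochondrial chromosome 2297 rows were tested, of which 16.3% were higher and 16.1% lower, and their reads need not come from the gene that the row names. The 2 highest and 2 lowest of them under the rule for named genes follow. The row at the place of INTS5 (chromosome 11, 62646848 to 62653302) had 60 and 133 reads in control medium and 1463 and 1264 in arginine-free medium. The row at the place of DSP (chromosome 6, 7541326 to 7586717) had 2 and 6 against 163 and 83. The row at TNFRSF10A (chromosome 8, 23190452 to 23225102) had 66 and 140 against 8 and 7, and that at ABCC4 (chromosome 13, 95019835 to 95301451) had 78 and 188 against 19 and 11.

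Of the 34 gene lists, 10 had at least 5 tested rows and 1, the histones, passed camera at the preset correlation. None passed with an estimated correlation, a form with little power at 2 libraries per group (histones, adjusted p = 0.625 with an estimated correlation). The lists that did not pass included the amino acid stress response targets (adjusted p = 0.542), the cytosolic aminoacyl-tRNA synthetases (0.752), the amino acid carriers (0.865) and nuclear-encoded oxidative phosphorylation (0.258). The last of these passed fry, which tests a list by itself and not against the other rows (lower, adjusted p = 0.0072). Most members of these lists lie outside the stretches, so the tests say little about the pathways. The genes named in advance could not be followed. The rows of ASL, SLC7A1, ATF4, DDIT3, SLC7A11, SESN2, RARS1, MITF and CDKN1A were listed at 0 in all 4 libraries, the row of ASS1 held 7 reads in all, and no row was matched to ASNS or TRIB3.

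The share of counts on histones was 2.32% ± 0.204 in control and 0.554% ± 0.047 in arginine-free medium (SD, n = 2 each), and that on ribosomal protein rows was 1.05% ± 0.16 and 1.67% ± 0.0111, where RPS15, RPS6 and RPL37 alone held 9821 of the 10384 reads. Mitochondrially encoded proteins took 1.45% ± 0.249 and 0.86% ± 0.384 (SD, n = 2 each). A single row, that of the mitochondrial valine tRNA, took 14.5% ± 8.02 and 9.48% ± 1.13 (SD, n = 2 each), a difference within the spread between libraries, and 20.2% in control replicate 2 (95% Wilson interval 20 to 20.4). With 2 libraries against 2, an exact two-sided permutation test of a share cannot give a p-value under 33.3%.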

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

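The alternatives were fixed in advance, except nuclear rows alone, stretch rows alone, list members in the stretches alone and stretches found without the lists of stress-induced genes, which were added after seeing the data. No named gene reversed direction where it was past the threshold. Of 1157 values for 76 named rows, 1060 stayed on their side of the threshold, 70 no longer passed and 27 newly passed. The cause was not tested, although fewer rows or a stricter question entered some settings by construction. Higher and lower rows over the table numbered 138 and 146 with at least 50 counts in every library of a group, where 580 rows were tested. Of these 146 lower rows, 106 were also lower in the main test, so fewer rows was not the only change. The log2 fold changes of RNR1 and ND2 were lower with that filter, at 0.84 and -1.10 against 1.09 and -0.88. Higher and lower rows numbered 231 and 274 against a fold of 1.5. Against that fold the calls ended for EEF2, THOP1, SF3A2, MIDN, MAP2K2, SDHA, COX1, ND2, ATP6, RNR1 and 4 mitochondrial tRNAs (adjusted p from 0.0561 to 0.212). They numbered 259 and 285 among protein-coding nuclear rows and 162 and 147 with DESeq2. In the stretches the higher rows were 14, 17 and 12 with the stricter filter, the fold of 1.5 and DESeq2, and the lower ones 25 with the stricter filter and 28 with DESeq2. Leaving out 1 library gave 270 to 418 higher and 243 to 389 lower rows, and 18 to 32 higher and 39 to 47 lower rows in the stretches. The fewest lower rows over the table (243) and higher rows in the stretches (18) came without control replicate 2. In the stretches found without the lists of stress-induced genes, 23 rows were higher and 40 lower of 166 tested, and VLDLR, PLIN2, TYRP1, FREM1 and BNC2 lay outside.

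The lists past the threshold numbered 0 with an estimated correlation, 2 with fry (histones and nuclear-encoded oxidative phosphorylation) and 2 with camera on ranks (histones and mitochondrially encoded proteins), and 1 to 2 with a library left out. The histone list kept a median of -3.11 but lost its call with an estimated correlation (adjusted p = 0.625), where the test has little power with 2 libraries per group. With a library left out its median ran from -3.08 to -2.46. The mitochondrially encoded list passed on ranks (median -0.62, adjusted p = 0.00921), and its median ran from -1.0 to -0.30 with a library left out. It passed without control replicate 2 (median -0.67, adjusted p = 0.0297) and without arginine-free replicate 1 (adjusted p = 0.000115). These 3 calls are at the preset correlation, and the list had adjusted p = 0.918 with an estimated correlation. With the replicate number as a block (replicate block), 354 rows were higher and 372 lower, the histone median was -3.11 and 1 list passed. Deviations of libraries with the same number had a correlation of -0.05. With 2 libraries per group this is 1 value, and counting noise can pull it towards 0. It cannot tell whether the numbers pair the libraries. The arginine content comparison and its alternatives were not run. With these libraries 22% of simulated 2-fold changes were recovered, so rows that did not pass are not shown to be unchanged.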

Other observations

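Rows of mitochondrial RNAs that are not translated also moved, and these rows were chosen after their values were seen. The tRNA rows are short and were counted without strand. If reads were placed on another build, their reads need not come from the tRNA named. Of 18 tested mitochondrial tRNA rows, 9 were past the threshold in arginine-free medium, all lower. TRNM, not past it with all 4 libraries, went the other way, with log2 fold changes from 0.17 to 1.57 over the alternatives. Of these 9, 5 were still past it without control replicate 2 and 4 with DESeq2, since TRNI, TRNY, TRND and TRNP were lost in both and TRNK with DESeq2 (adjusted p = 0.0737). Without control replicate 1, arginine-free replicate 1 and arginine-free replicate 2, 7, 6 and 8 were. The cysteine tRNA TRNC went from 735 ± 53.3 to 130 ± 24.2 CPM (SD, n = 2 each, log2 fold change -2.47, SE 0.26, edgeR adjusted p = 8.48e-06). TRNL1, TRNH, TRNK and TRNE changed by -2.43 (SE 0.34), -2.14 (SE 0.28), -2.01 (SE 0.38) and -1.38 (SE 0.25). The ribosomal RNAs RNR1 and RNR2 rose, by 1.09 (SE 0.37) and 1.79 (SE 0.46), mostly in arginine-free replicate 2, which held 14467 RNR2 reads against 5538 in replicate 1. Without that library RNR1 stood at 0.52 and no longer passed (edgeR adjusted p = 0.114), and RNR2 stood at 0.59, against 2.5 without arginine-free replicate 1. RNR1 did not pass without control replicate 2 (edgeR adjusted p = 0.108), with the replicate number as a block (0.0967) or with the stricter filter (0.134). RNR2 did not pass with DESeq2 (adjusted p = 0.15) or the stricter filter (0.0667). TRNL1 stood at -1.84 without arginine-free replicate 1 and at -3.03 without arginine-free replicate 2.

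Further genes in the stretches were chosen after their values were seen, 1 by 1, and no list tests them as a group. FREM1 and BNC2 lie in the part of the chromosome 9 stretch that depends on VLDLR. The guidance receptor SEMA5A went from 267 ± 22.2 to 25.6 ± 0.608 CPM (SD, n = 2 each) and the growth hormone receptor GHR from 267 ± 8.31 to 23.6 ± 15.6 (SD, n = 2 each), where GHR had a log2 fold change of -3.35 and stood at -4.27 without arginine-free replicate 1. FREM1, of the extracellular matrix, changed by -2.55 (SE 0.41) and the zinc finger gene BNC2 by -2.05 (SE 0.39), on the log2 scale, and BNC2 did not pass with DESeq2 (adjusted p = 0.0593). DOHH, the second enzyme of the hypusine modification of eIF5A, which uses the polyamine spermidine, was higher by 1.73 (SE 0.41), a call that ended without control replicate 2 (edgeR adjusted p = 0.0729) and with DESeq2 (adjusted p = 0.064). MAP2K2, a kinase of the MAPK pathway, was lower at -0.91 (SE 0.23), and the call ended without control replicate 1 (edgeR adjusted p = 0.165) and with DESeq2 (adjusted p = 0.143).

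The tests of the first pattern, and for the second all but the libraries left out, were chosen after the results were seen. The bounds that each test was held to were also set afterwards. The first pattern is the broadly expressed genes listed at 0. Low depth is argued against by the ribosomal protein rows. Of these, 52 of 72 were at 0, while 3 held 1517 to 4943 reads each. The 3 lie inside the stretches, where by definition no ribosomal protein row could be at 0, so their place adds nothing. Loss of reads that fit several places is argued against as the whole cause, since 61.8% of 68 proteasome, mitochondrial ribosome and tRNA synthetase genes without a named pseudogene were at 0, against 75.4% of the 61 with one. Genes that held reads lay side by side, with 33 genes in runs of 5 or more, against at most 16 in 10000 shuffles (permutation p = 0.0001, the smallest they can give), 32 against at most 11 without the lists of stress-induced genes, and 16 against at most 10 without histones. A candidate explanation is that reads placed on GRCh37 were counted over exons on GRCh38, and no biological explanation was tested.

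For the second pattern, the fall of the histone rows, a scaling of the libraries moves all rows alike and is argued against, since the histone median in the stretches minus that of the other 180 tested rows there was -3.25. The lowest median of as many of those rows in 10000 random draws was -1.29. Rows drawn at random do not stand for neighbouring near-identical copies, so these draws do not test the histone fall. A single library is argued against, since the histone median was at least as low as -2.46 whichever library was left out. Summed over all histone rows, the share in arginine-free medium was 23.9% of control, but 19 of 39 rows were at 0, so reads moving to copies that cannot be read stay open. Fewer cells copying their DNA may account for the fall, and the 1 readable replication gene, CHAF1A at -0.91 (edgeR adjusted p = 0.208), cannot decide it.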
